A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

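Poly(A) RNA of Saccharomyces cerevisiae BY4741, a haploid laboratory strain of mating type a, was sequenced in 4 libraries. All carried a CRISPR interference system, in which a catalytically dead Cas9 protein bound at a guide-specified site blocks transcription there. Per the labels, 2 libraries carried a guide with a scrambled sequence and 2 carried the guide named +116, which inhibits the noncoding RNA of the GAL10 gene. The cultures grew in synthetic medium with glucose and without leucine or uracil, from an optical density of 0.1 to 0.4. RNA was extracted with hot phenol and treated with DNase, and the libraries were made with a stranded mRNA kit. The 2 libraries of each group bear the letters A and B. The series' design text speaks of strains, and nothing more is said of how the A and B cultures were started, so each p-value measures the spread between these libraries only.

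The authors deposited 1 table with 1 column per library and 1 row per gene. Per the submitters' processing notes, the tools were bcl2fastq 1.8.4, Trimmomatic 0.30, TopHat, TopHat2 2.0.8, Bowtie2, Picard 1.84 and DESeq2, named without roles. The genome build, the annotation, the read counter and the strand setting of the count are not given in the sources used here, so no genome coordinates are printed. The deposited values are a normalized read count, a signal that is never negative: gene counts that the authors divided by 1 size factor per library. This unit was tested on the values. In each column 100% of the values were whole multiples of 1 step, within a tolerance of 1e-06 of a read, and the steps gave size factors of 1.11 and 0.913 for scrambled A and B and 1.00 and 0.994 for +116 A and B. DESeq2 size factors recomputed from the recovered whole reads over all rows gave back the deposited scaling. No column of the table was left unused.

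The recovered reads summed to 40628383 and 34215480 for scrambled A and B, and to 37077366 and 36731031 for +116 A and B. The 10 genes with the most reads took 11.6% to 11.9% of each library. Of 7126 rows, 263 were at 0 in all libraries. The 54 rows of mitochondrial genes were all among these. Row identifiers were matched to the R64 assembly of the RefSeq annotation, used for names, neighbour order, length and GC content. By locus tag 6048 rows matched, by name of a noncoding gene 114 matched, and 964, mostly dubious reading frames and transfer RNA genes, did not. Of the matched lengths of tested genes, 95.4% were multiples of 3, so the lengths are largely coding lengths without untranslated regions. Introns are counted in them, in 268 of 5891 tested genes with a length. With introns left out, 98.2% were multiples of 3.

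Whether the counts keep the strand was examined in genes that lie wholly inside another gene. Of 43 genes nested on the same strand as the outer gene, 2 had reads, at a median of 0 over the 43. All 8 genes nested on the opposite strand had reads. ADF1, for example, averaged 992 normalized reads inside FYV5, which averaged 21.3. The counts thus kept the strands apart in these genes, although no source states the setting. Near-identical copies, such as CUP1-1 and CUP1-2, the Ty reading frames, and HMRA1 with its copy at the mating type locus, can share reads, and their values are uncertain.

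Before the data were examined, the groups, the tests, 34 gene lists, the rule for named genes and the alternatives were fixed. The table held normalized values, for which the design set limma 3.58.1 (R 4.3.3), so that test was used as designed. Genes with a mean of at least 5 over the 4 libraries entered a limma fit with a mean-variance trend on log2(value + 1). The tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all tested genes, and the threshold was an adjusted p of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Values are given as mean ± SD of 2 libraries and log2 folds with the limma standard error (SE). Gene lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists, and again with an estimated correlation. With an estimated correlation the test has only the residual degrees of freedom of 4 libraries, so it has little power to pass a list. Members were also counted at a threshold adjusted over the list alone. The lists covered the GAL regulon and the neighbours of GAL1, selection markers and auxotrophies, amino acid and nucleotide synthesis, carbon use and respiration. They also covered stress and protein folding, ribosomes and their assembly, metal and phosphate uptake, sterols, histones and the cell cycle. The rest held mating types, sporulation, drug and oxidative stress, and chromatin and RNA termination factors.

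Named genes were all members of the lists of the GAL regulon, the GAL1 neighbours and the markers, and the 10 largest changes in each direction among genes past the threshold whose groups did not overlap. To these were added, from each other list past the list threshold or with a called member, up to 4 members with the lowest p. SLM4 stood in the list of GAL1 neighbours by error and does not neighbour GAL1 in R64. Apart from the examples of strand and of shared reads given above, genes named outside this rule are marked as chosen after their values were seen. One gene that the rule names is not reported here.

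The alternatives fixed in advance were pseudocounts of 0.5 and 8, no filter and a mean of at least 50, limma without a trend, robust empirical Bayes, upper-quartile and TMM scaling, the library letter as a block, and leaving out each library in turn. On the recovered whole reads, edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0 were run as further alternatives. A correction for gene length, 1 for length and GC content together, and 1 for spliced length, with introns left out, were added after the data were seen. In these a loess curve with a span of 0.5 was removed from each library's log2 deviations. Genes for which DESeq2 gave no adjusted p were left without one.

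The fit was tested on simulated counts of 6249 genes drawn from the library means, with 50 genes changed at each of 4 sizes. A further list of 40 genes was raised 1.25-fold together. The fit called 72% of the single genes changed 1.25-fold, 80% at 1.5-fold, 96% at 2-fold and 100% at 4-fold, 174 in all. With 24 calls among the genes of the raised list and 8 false calls this made 206. The raised list reached a camera adjusted p of 1.797e-14 and 0 of 20 unchanged lists passed. In this step the simulated genes varied independently, with no length trend and a spread set by the mean count alone. These rates may therefore not hold for the real libraries. A length slope of 0.15 per doubling put into the simulation was estimated at 0.143 before the correction and at −0.0046 after it. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the table and drew the figures.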

Results

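Gene expression was measured by RNA sequencing in yeast cells carrying a CRISPR interference system with 1 of 2 guides, 2 libraries for each. In the scrambled libraries the guide had a scrambled sequence. In the +116 libraries the guide inhibits the GAL10 noncoding RNA, a transcript known to run antisense to GAL10 in cells grown on glucose, on the strand of GAL1. The cells grew on glucose, where the GAL genes for galactose use are repressed, to an optical density of 0.4. The libraries held 34215480 to 40628383 gene-assigned reads, and 6277 genes were abundant enough to test. The comparison of the guides asks which transcripts differ, at the GAL locus and across the genome, when this noncoding RNA is inhibited.

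At the GAL locus, GAL1 was lower and GAL10 higher with the +116 guide. GAL1 (YBR020W), which encodes galactokinase, fell from 439.8 ± 41.3 normalized reads (SD, n = 2) with the scrambled guide to 124.3 ± 12.3 (SD, n = 2). This was 3.52-fold lower, a log2 fold of −1.81 with an SE of 0.118 (limma adjusted p = 3.7e-06), and the lowest p of all genes tested. GAL10 (YBR019C), which encodes the epimerase of the pathway, rose 1.74-fold, from 103.9 ± 12.7 to 181.5 ± 14.9 normalized reads (SD, n = 2), a log2 fold of 0.80 with an SE of 0.142 (limma adjusted p = 0.0403). GAL7 (YBR018C), the transferase gene beside GAL10, had 114.6 ± 9.89 and 118.9 ± 18.2 normalized reads (SD, n = 2), a log2 fold of 0.05 with an SE of 0.156. With the +116 guide the normalized count of GAL1 was thus near that of GAL7, and with the scrambled guide it was above those of GAL7 and GAL10 in both libraries. These counts are not divided by gene length, so they do not rank the levels of these transcripts. The genes are 1587 bp (GAL1), 1101 bp (GAL7) and 2100 bp (GAL10) long. The GAL1 call was lost without scrambled A (limma adjusted p = 0.0511) and without scrambled B (0.103), at log2 folds of −1.91 and −1.72, and in limma without a variance trend (0.135). The GAL10 call was lost without scrambled A and without scrambled B, at log2 folds of 0.68 and 0.92. It was also lost with no filter on low values (log2 fold 0.80, limma adjusted p = 0.0964), without a trend (0.80, limma adjusted p = 0.353) and after a correction for gene length (0.74, limma adjusted p = 0.214).

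In the R64 gene order KAP104, GAL7, GAL10, GAL1, FUR4, POA1 and CHS3 follow one another, with GAL10 and GAL7 on the opposite strand to GAL1. FUR4, the uracil permease gene next to GAL1, had 2978 ± 143.1 normalized reads with the scrambled guide and 3548 ± 119.5 with +116 (SD, n = 2), a log2 fold of 0.25. Its limma adjusted p of 0.05002 lay just above the threshold. CHS3, a chitin synthase gene 2 genes further on, had a log2 fold of 0.21 (limma adjusted p = 0.0559). Each was past the threshold in 6 of 18 alternatives, among them edgeR (adjusted p = 0.0356 and 0.0467) and DESeq2 (0.0204 and 0.0329), and neither was without scrambled A, without scrambled B or after any length correction. After the gene length correction the log2 fold was 0.20 for FUR4 and 0.11 for CHS3. The list of GAL1 neighbours, which holds GAL1 and GAL10, had 3 members higher and 1 lower adjusted over the list alone. The log2 folds of KAP104 (0.0035), POA1 (0.0067) and MNN2 (0.09) were smaller than 2 of their SEs. SLM4, which was listed with these genes but lies elsewhere, had 0.10 (limma adjusted p = 0.391).

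**Figure D1:**
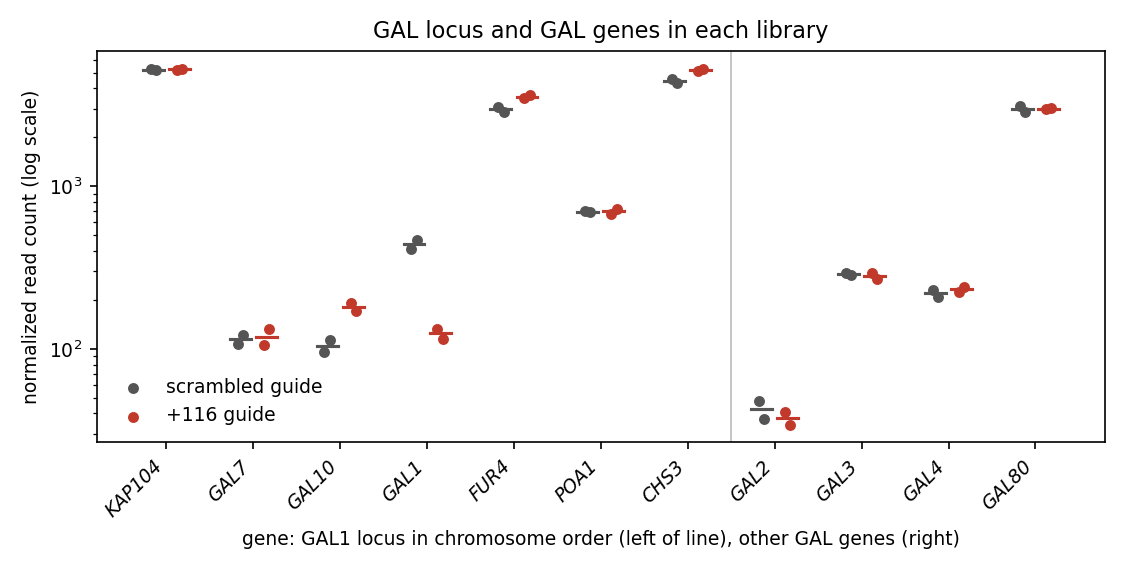
Normalized read counts (vertical axis, log scale) of 11 genes in the 2 scrambled (grey) and 2 +116 (red) libraries, where points are libraries and bars are group means. GAL1 lies at 410.6 and 468.9 with the scrambled guide and at 133.0 and 115.7 with +116, while GAL10 lies at 94.96 and 112.9 and at 192.0 and 171.0.

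The rest of the GAL regulon did not pass the test. Of 12 members, GAL1 was called lower, GAL10 was called higher and 10 were not called. The log2 folds of those 10 ranged from −0.17 to 0.12, and their lowest limma adjusted p was 0.253. GAL2, the galactose permease gene, had 42.6 ± 7.55 and 37.6 ± 4.81 normalized reads (SD, n = 2), too few for a difference of its size (log2 fold −0.17, SE 0.239) to be detected. The regulators GAL4, GAL80 and GAL3 had log2 folds of 0.09, 0.0057 and −0.05, and GCY1, PCL10, LAP3, MTH1 and PGM2 had 0.03, 0.02, 0.07, 0.02 and 0.12. As a list the regulon had a median log2 fold of 0.0240 (camera adjusted p = 0.845), and adjusted over the list alone the calls were again 1 higher and 1 lower.

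Among the listed marker and auxotrophy genes, URA3 was lower with the +116 guide and LEU2 and HIS3 were not called. URA3 and LEU2 allow growth of this strain without uracil and leucine, as in the medium used here. HIS3 was listed as an auxotrophy gene, and the medium is not described as lacking histidine. URA3 had 79470 ± 20713 normalized reads with the scrambled guide and 49794 ± 3902 with +116 (SD, n = 2), a log2 fold of −0.65 with an SE of 0.121 (limma adjusted p = 0.0413). The scrambled libraries differed from each other, at 94116 in A and 64823 in B. Without scrambled A the log2 fold was −0.38 (limma adjusted p = 0.148), and without scrambled B it was −0.92 (0.107). In all, 9 of 18 alternatives kept the URA3 call, and it was also lost with DESeq2 (adjusted p = 0.130), with robust empirical Bayes, with no filter, without a trend and after all 3 length corrections, at log2 folds of −0.59 or below. LEU2 had 215090 ± 25750 and 206161 ± 16253 normalized reads (SD, n = 2), with a log2 fold of −0.06, and HIS3 had −0.01. MET17, which is deleted in this strain, was at 0 reads in all 4 libraries. This list of 4 genes had 3 tested members and a camera adjusted p of 0.142.

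Across the genome, 53 of 6277 genes passed the limma threshold, 32 higher and 21 lower with the +116 guide, and 1366 had an unadjusted p under 0.05. The changes were mostly small. The median called gene was 1.24-fold higher or 1.29-fold lower, and 7 called genes had a log2 fold beyond 0.5 in size. These 7 were GAL1, GAL10, URA3, CUP1-1, CUP1-2, YDR133C and snR49. All 53 had no overlap between the groups' values, which largely follows from the low p that a call needs. Of the tested genes 53.5% had no overlap, against the 33.3% that a random order of the libraries gives. Trends shared by many genes, such as that with gene length below, can raise this share. The count moved with the fit. Limma called 0 higher and 0 lower without scrambled A and likewise without scrambled B, where 1341 and 448 genes had an unadjusted p under 0.05. It called 132 and 104 without +116 A, and 207 and 75 without +116 B. The counts were 28 and 54 with upper-quartile scaling, 106 and 60 with edgeR, 100 and 80 with DESeq2, and 0 and 1 in limma without a trend.

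Among genes past the threshold, the largest falls after GAL1 were in YDR133C and URA3. YDR133C, a reading frame with no match in the RefSeq annotation, fell from 123.8 ± 1.48 to 53.1 ± 15.4 normalized reads (SD, n = 2), a log2 fold of −1.23 (limma adjusted p = 0.0207). The metallothionein genes CUP1-1 and CUP1-2, near-identical copies that can share reads, fell by 0.55 and 0.53 on the log2 scale, CUP1-1 from 58257 ± 1381 to 39830 ± 512.2 normalized reads (SD, n = 2). Lower log2 folds past the threshold were also measured for the small nucleolar RNAs snR49 (−0.64) and snR33 (−0.36). Poly(A) RNA was sequenced, so these values may not follow the total levels of such RNAs. SPC29 (−0.38), a spindle pole body gene, and YGR182C (−0.37), which had no match in the annotation, were also lower. So was RPL35A (−0.37), which encodes a protein of the large ribosomal subunit.

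Among genes past the threshold, the largest rises after GAL10 were in YJR154W (log2 fold 0.49), BFA1 (0.46), a gene of the mitotic exit checkpoint, and ATG15 (0.41), which encodes a vacuolar lipase. PRY3, a cell wall gene, rose from 3189 ± 97.1 to 4190 ± 5.15 normalized reads (SD, n = 2), a log2 fold of 0.39 (limma adjusted p = 0.0043). DIP5, an amino acid permease gene, HKR1, a cell wall sensor gene, and AIM17 had log2 folds of 0.35, 0.35 and 0.35. The same list of rises held YLR256W-A and YAR010C, reading frames of Ty1 retrotransposons, at 0.35 and 0.35. Their many copies can share reads.

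**Figure D2:**
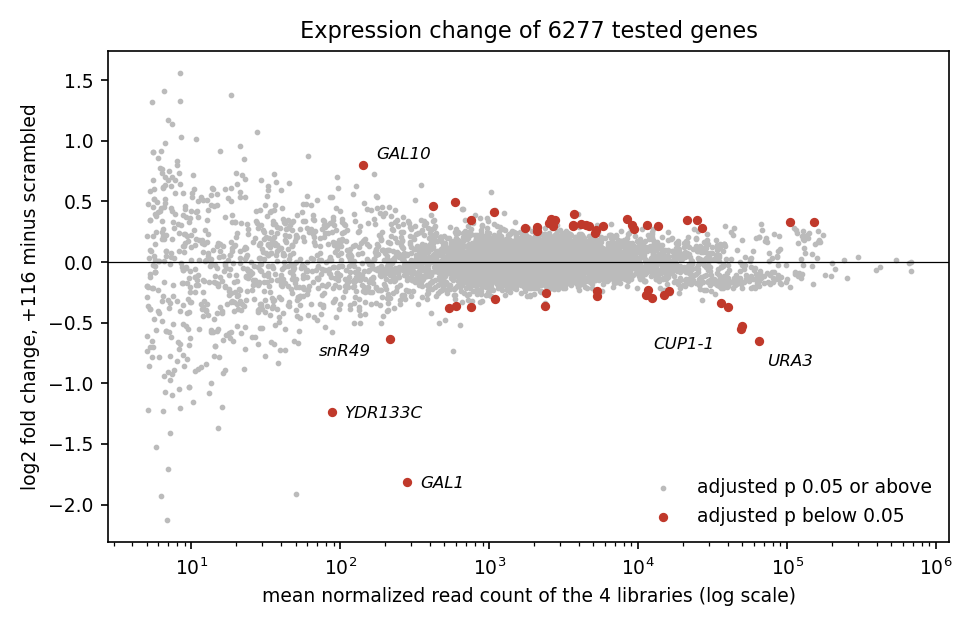
Log2 fold change, +116 minus scrambled (vertical axis), against the mean normalized read count of the 4 libraries (horizontal axis, log scale) for the 6277 tested genes. Red points are the 53 genes past the limma threshold. GAL1 at −1.81 and YDR133C at −1.23 lie lowest among them, and GAL10 at 0.80 highest.

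Expression differences followed gene length. Across 5891 tested genes with a length, the log2 fold correlated with length at a Spearman rho of 0.546 (across genes, which are not independent replicates) and rose by 0.0568 per doubling of length. When the genes were divided by length into 10 bins of equal size, the bin of the shortest genes (median 303 bp) had a median log2 fold of −0.12, and that of the longest (median 3675 bp) had 0.11. Genes called higher had a median length of 2541 bp, genes called lower 753 bp and tested genes 1206 bp. Libraries of 1 group differed in the same manner, by −0.026 per doubling from scrambled A to B and 0.024 from +116 A to B, and pairs across the groups by 0.031 to 0.082. After a length correction the 51 called genes with a length all kept their direction, and their median absolute log2 fold went from 0.314 to 0.236. GAL1 alone among them was past the limma threshold, whose prior degrees of freedom went from 11.5 to 5.66, and that drop alone left 8 of the 51 at the p of the last called gene. With GC content corrected too, GAL1 and HPF1 passed, the latter a cell wall mannoprotein gene named after its values were seen.

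**Figure D3:**
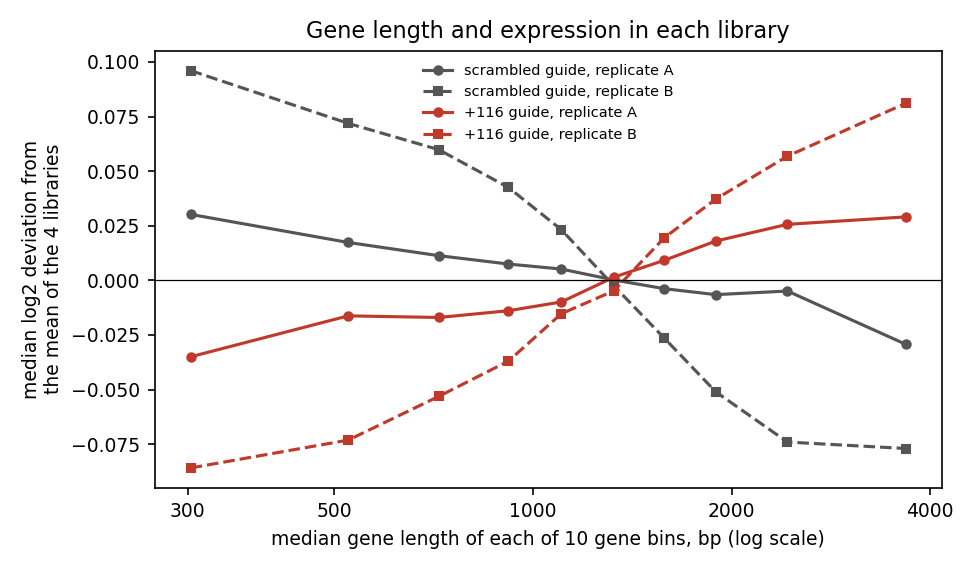
Median log2 deviation from the mean of the 4 libraries (vertical axis) for 10 bins of genes by length (horizontal axis, bp, log scale), 1 line per library. The bin of the shortest genes lies at 0.030 and 0.096 in scrambled A and B and at −0.035 and −0.086 in +116 A and B, and that of the longest lies on the other side of 0 in each library.

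Of the 34 gene lists, 11 passed the camera threshold at the preset correlation, 5 higher and 6 lower, and 0 passed with an estimated correlation, where 1 list had an unadjusted p under 0.05. The latter setting has only the residual degrees of freedom of 4 libraries, so missing its threshold does not show that a list is unchanged. The preset correlation in turn treats the genes of a list as nearly independent. Where genes vary together between libraries, its p-values are too small and overstate the evidence. Targets of Gcn4, the activator of amino acid synthesis genes, were higher, with 27 of 28 members above 0 and a median log2 fold of 0.16 (camera adjusted p = 2.1e-07, adjusted p = 0.745 with an estimated correlation). LYS2 (0.30), of lysine synthesis, and ARO1 (0.29), of aromatic amino acid synthesis, were called, and 4 members adjusted over the list alone. The ARG5,6 gene had a log2 fold of 0.25 without passing. The related list of leucine and branched-chain amino acid synthesis had 13 of 14 members above 0 and a median of 0.10 (camera adjusted p = 0.0066, adjusted p = 0.686 with an estimated correlation). None of its members was called and 1 was adjusted over the list alone, with LEU4 at 0.28, BAP2 at 0.17, BAP3 at 0.16 and ILV2 at 0.13. After the length correction the Gcn4 list passed (median 0.14) and the leucine list did not (median 0.056, camera adjusted p = 0.0697). Without +116 A neither list passed, with medians of 0.031 for Gcn4 targets (camera adjusted p = 0.444) and 0.051 for the leucine list (0.245), and the leucine list also missed the threshold without scrambled A (0.0513). Without +116 B the medians were 0.28 and 0.15.

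Genes of the general stress response, induced by Msn2 and Msn4, were also higher as a list, with 23 of 25 members above 0 and a median log2 fold of 0.13 (camera adjusted p = 2.0e-05, adjusted p = 0.686 with an estimated correlation). TSL1, of trehalose synthesis, rose by 0.30 and was the 1 called member, against 6 adjusted over the list alone. HSP42, GSY2 and TPS2 had log2 folds of 0.24, 0.23 and 0.20. The list passed after the length correction too, at a median of 0.15. The iron regulon had 20 of 24 members above 0 and a median of 0.09 (camera adjusted p = 0.0155, adjusted p = 0.791 with an estimated correlation), with 0 called over all genes and 0 adjusted over the list alone. FIT3 (0.40), FRE2 (0.31), ENB1 (0.18) and ARN2 (0.18) had its lowest p-values. The FIT3 value was −0.031 without +116 A and 0.84 without +116 B. The iron list lost its call without scrambled A (median −0.0016, camera adjusted p = 0.968), without +116 A (0.021, 0.880) and after length with GC content (0.07, 0.0588), and its median was 0.14 without scrambled B and 0.14 without +116 B. Genes of G2/M and M/G1 had a median of 0.06 (camera adjusted p = 0.0065, adjusted p = 0.686 with an estimated correlation), with 0 called and 5 adjusted over the list alone. EGT2 (0.27), CTS1 (0.25), DSE4 (0.22) and DSE2 (0.16), which act in the separation of daughter cells, led it. This list did not pass after the length correction (median 0.031, camera adjusted p = 0.233), nor without scrambled B (median −0.0008), and its median was 0.10 without scrambled A.

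Cytosolic ribosomal protein genes were lower, with all 138 members below 0 and a median log2 fold of −0.16 (camera adjusted p = 1.7e-37, adjusted p = 0.686 with an estimated correlation). Called members numbered 6, among them RPL35A (−0.37), RPL41A (−0.34), RPL36A (−0.30) and RPL33B (−0.24), and 103 adjusted over the list alone. The list's median length was 771 bp with introns, which 89 members have, and 433.5 bp without. The length correction left a median of −0.09, and with introns left out of the lengths −0.06 (camera adjusted p = 5.2e-14). Ribosome biogenesis genes, with a median length of 1605 bp, had 54 of 63 members below 0 and a median of −0.06 (camera adjusted p = 3.4e-06, adjusted p = 0.686 with an estimated correlation). None was called or adjusted over the list alone, and IMP3 (−0.24), RLP24 (−0.20), CIC1 (−0.18) and NOP15 (−0.18) had the lowest p-values. The length correction left a median of −0.09 for this list, past the threshold.

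The copper regulon had the lowest median, −0.23 over 8 members (camera adjusted p = 0.0014, adjusted p = 0.686 with an estimated correlation). Its called members were CUP1-1 and CUP1-2, and 5 were lower and 1 higher adjusted over the list alone. These near-identical copies can share reads, so the list test and this count may take 1 measurement as 2 members. CRS5, another metallothionein gene, had −0.23 and SOD1, the copper-zinc superoxide dismutase gene, −0.17. Histone genes had 10 of 10 members below 0 and a median of −0.15 (camera adjusted p = 2.8e-05, adjusted p = 0.686 with an estimated correlation), with 0 called and 7 adjusted over the list alone. HTA2 and HTA1 had log2 folds of −0.25 and −0.23, HTB1 −0.20 and HHF1 −0.16. The respiratory chain list had 25 of 33 members below 0 and a median of −0.08 (camera adjusted p = 7.2e-04, adjusted p = 0.686 with an estimated correlation), with COX7 at −0.20, QCR8 at −0.19, COX13 at −0.17 and NDI1, a longer gene, at 0.22. Mitochondrial ribosomal protein genes had a median of −0.06 (camera adjusted p = 0.0034, adjusted p = 0.791 with an estimated correlation), with MRPL31 at −0.23, MRPS16 at −0.22, MRPL50 at −0.17 and MRP10 at −0.15. These last 2 lists had 0 members called or adjusted over the list alone. The mitochondrial ribosomal list lost its call without scrambled B (median −0.027, camera adjusted p = 0.0753) and without +116 B (−0.014, 0.474), and its median was −0.098 without +116 A. The respiratory median was −0.053 without +116 A and the histone median −0.098 without scrambled B, both past the camera threshold. The median lengths of the histone, respiratory and mitochondrial ribosomal lists were 399, 468 and 699 bp. None of the 3 passed after the length correction, with medians of −0.04, −0.01 and 0.02, while the copper regulon passed at −0.12.

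**Figure D4:**
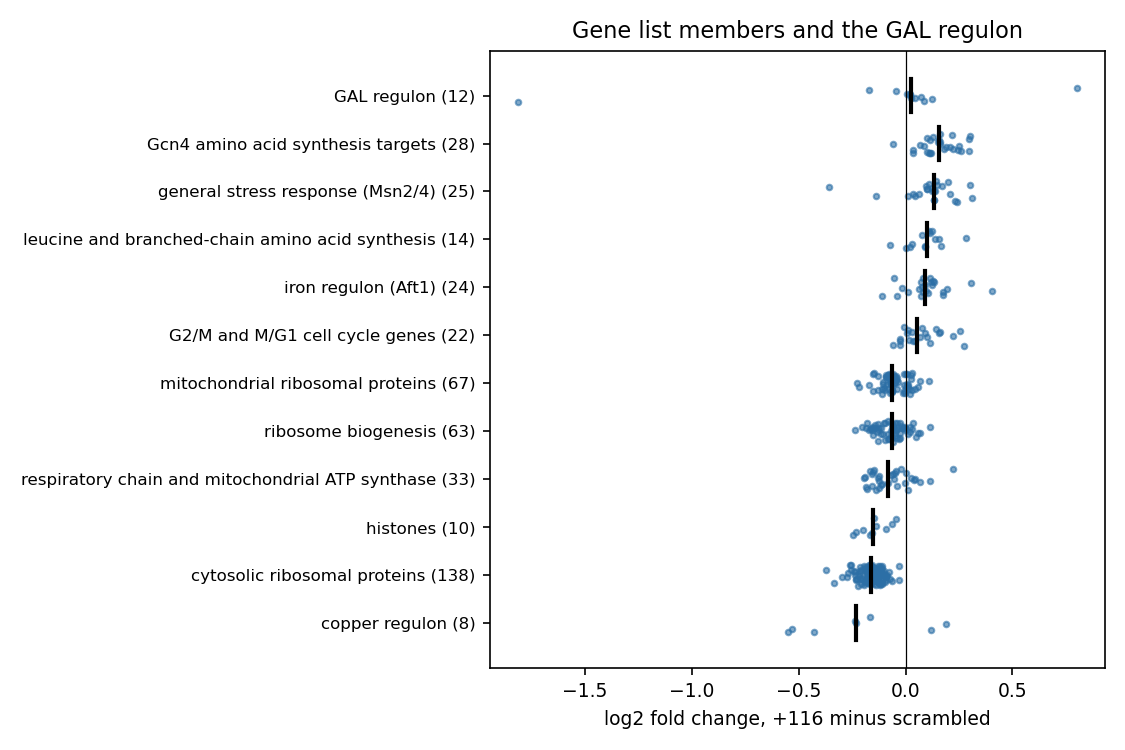
Log2 fold change, +116 minus scrambled (horizontal axis), of each member (points) of the 11 lists past the camera threshold and of the GAL regulon, with list medians as black bars and the number of tested members in parentheses. All 138 cytosolic ribosomal protein genes lie below 0, and the GAL regulon lies near 0 apart from GAL1 and GAL10.

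The other 23 lists did not pass at the preset correlation. The closest was multidrug resistance (camera adjusted p = 0.0506, median log2 fold 0.14), in which SNQ2, a drug efflux pump gene, rose by 0.27, PDR15 and TPO4 had 0.27 and 0.21, and GRE2 −0.28. Glucose-repressed carbon genes had a median of 0.07 and 2 called members, the regulator ADR1 (0.32) and the hexokinase HXK1 (0.31), with GLK1 at 0.17 and SFC1 at −0.65. Of the zinc regulon (median −0.08), the transporter gene ZRT1 rose by 0.28, with ZAP1 at 0.23, ZRT2 at 0.13 and ZRT3 at 0.12. Of the heat shock list (median 0.0095), HSP78 rose by 0.30, with HSP104 at 0.19, FES1 at −0.18 and MDJ1 at 0.12. The medians were 0.09 for the GAL1 neighbours, 0.08 for hexose transporters, −0.0099 for glycolysis, −0.0064 for uracil synthesis, 0.0043 for methionine and sulfur, −0.01 for the unfolded protein response and 0.05 for the phosphate regulon. They were −0.01 for ergosterol synthesis, −0.03 for G1/S genes, 0.01 for DNA damage genes, −0.07 for oxidative stress, −0.07 for seripauperin and cell wall genes and 0.06 for chromatin and termination factors linked to this noncoding RNA. Among markers of other cell types, genes of mating type alpha cells had a median of −0.04 (camera adjusted p = 0.658, 1 of 4 lower adjusted over the list alone) and sporulation genes −0.02 (0.950). Among those of the strain's own type, genes of mating type a cells had −0.0060 (camera adjusted p = 0.836, 1 higher and 1 lower adjusted over the list alone) and haploid and mating genes −0.01 (0.539, 1 higher). The mean log2 fold had the other sign than the median for the GAL regulon (−0.07), the GAL1 neighbours (−0.03), uracil synthesis (0.0079) and the haploid and mating genes (0.03), and the zinc regulon ranked upward in camera with a median and mean below 0.

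Libraries of 1 group were close to each other. The median absolute log2 difference per gene was 0.0716 between the scrambled libraries, 0.0680 between the +116 libraries and 0.0764 to 0.12 between libraries of different groups. Spearman correlations across genes were 0.996 to 0.998 for all pairs. Chi-square values per degree of freedom were above 10 within both groups, so no library repeated another within counting noise.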

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

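The 3 corrections for gene length, alone, with GC content and with introns left out (spliced length), were chosen after the data were seen, and all other alternatives were planned. Of 1912 values of 109 results under the alternatives, 1465 kept their direction and side of the threshold, 246 kept only the direction, 130 crossed to the called side in the same direction, 35 moved and 36 changed sign. With a pseudocount of 0.5 and with TMM scaling all 109 stayed as reported. With 2 libraries per group each call rests on a spread shared across genes, and the counts of calls moved with how that spread was estimated. Apart from settings named here, the cause of each move was not tested.

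The 32 genes higher and 21 lower became 20 and 12 with a pseudocount of 8, and 2 and 5 with no filter on low values, all among the original calls. They became 82 and 55 with a mean of at least 50, where fewer genes were tested, and 245 and 165 with robust empirical Bayes. Limma without a trend called 0 and 1, and that 1 was not among the 21, with 868 genes at an unadjusted p under 0.05. Upper-quartile scaling gave 28 higher and 54 lower, and it moved the median of all genes to −0.02. On whole reads edgeR called 106 and 60 and DESeq2 100 and 80. The gene length correction called 0 and 1, length with GC content 0 and 2 and spliced length 0 and 1, with 819, 755 and 774 genes at an unadjusted p under 0.05. Leaving out 1 library each gave 0 to 207 higher and 0 to 104 lower. Both counts were 0 without scrambled A or without scrambled B, against 132 and 104 without +116 A and 207 and 75 without +116 B. In these fits the lone library was taken to vary like the pair of the other group. Of the 11 lists, 6 passed after the gene length correction, 5 after length with GC content, 6 after spliced length and 0 with an estimated correlation. The lists were not tested with edgeR or DESeq2. Under the other settings 9 to 13 of all 34 lists passed, which held all 11 where no library was left out, 9 without scrambled A, 9 without scrambled B, 8 without +116 A and 10 without +116 B.

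With the library letter as a replicate block, 170 genes were higher and 88 lower, including all 32 and all 21. The A minus B differences of the 2 groups correlated at −0.041 across genes, which gives no sign of a tie between equal letters. A tie cannot be excluded by this value, because the length trend from A to B ran in opposite directions in the 2 groups. It was −0.026 per doubling in the scrambled and 0.024 in the +116 libraries. The block kept the GAL1 and GAL10 calls. It brought 19 results past the threshold, among them FUR4 (limma adjusted p = 0.0109) and CHS3 (0.0365).

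The GAL1 log2 fold lay between −1.91 and −1.71 with 1 library left out, and it was −1.81 without a trend, where its limma adjusted p of 0.135 was the highest of 17 alternatives, of which 14 kept the call. GAL10 lay between 0.68 and 0.92 with 1 library left out. It missed the limma threshold without scrambled A or B, with no filter (0.80), without a trend (0.80), after the gene length correction (0.74), after length with GC content (0.73) and after spliced length (0.74), and 10 of 17 alternatives kept its call, with adjusted p-values from 5.6e-05 to 0.353. DESeq2 gave GAL1 and GAL10 no adjusted p, since its filter on mean counts removed them. Their unadjusted DESeq2 p-values were 5.5e-25 and 3.6e-04.

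Most changes of sign were of log2 folds near 0 that had not passed the threshold. Exceptions were FIT3, reported at 0.40 without a call, and the medians of 4 called lists. With upper-quartile scaling GAL80 was at −0.016, PCL10 at −0.0015, KAP104 at −0.018 and POA1 at −0.015. After the gene length correction KAP104 was at −0.086, HIS3 at 0.062 and the mitochondrial ribosomal median at 0.020. After length with GC content GAL80 was at −0.0025, GAL4 at −0.014, KAP104 at −0.087, HIS3 at 0.022, and the respiratory and mitochondrial ribosomal medians at 0.0017 and 0.028. After spliced length KAP104 was at −0.086, HIS3 at 0.059 and the mitochondrial ribosomal median at 0.019. With 1 library left out, the ranges that crossed 0 were −0.11 to 0.20 for GAL7, −0.35 to 0.0072 for GAL2, −0.11 to 0.017 for GAL3, −0.055 to 0.066 for GAL80, −0.025 to 0.068 for MTH1 and −0.022 to 0.062 for PCL10. They were −0.015 to 0.022 for KAP104, −0.042 to 0.055 for POA1, −0.18 to 0.064 for LEU2, −0.17 to 0.15 for HIS3 and −0.031 to 0.84 for FIT3. The list medians ran from −0.0016 to 0.14 for the iron regulon and from −0.00079 to 0.10 for G2/M and M/G1 genes. Depth limits the low genes most, such as GAL2 with its SE of 0.239.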

Other observations

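The length corrections, the breakdown of the calls they ended, and the tests of library scaling, of the single scrambled library with high URA3 and of LEU2 copy number were chosen after the results were seen, as were the groups and single genes described next, for which no test of the group was run. Of 67 small nucleolar and nuclear RNAs tested, 50 had a log2 fold below 0, with a median of −0.31, and 2 were called lower, snR49 and snR33, with 0 called higher. Their median length was 161 bp, at the low end of the length trend. Their median log2 fold was nevertheless below the lower quartile (−0.21) of the bin of the shortest genes. How much of it goes with length was not tested. Since poly(A) RNA was sequenced, the values of these RNAs may not follow their total levels. Of 49 Ty retrotransposon reading frames tested, with a median length of 5269 bp, 38 had a log2 fold above 0, with a median of 0.18, and 4 were called higher and 0 lower by limma. Near-identical copies can share reads, so these may not be separate measurements. TLC1, the telomerase RNA, fell by 0.36 on the log2 scale (limma adjusted p = 0.0138), again as measured in poly(A) RNA. HMRA1, a copy of the mating type a1 gene, fell by 0.31 (limma adjusted p = 0.0477) and AAH1, an adenine deaminase gene, by 0.28 (limma adjusted p = 0.0413). The anaerobic cell wall gene DAN1 differed between the +116 libraries, with 3.0 normalized reads in A and 72.4 in B, against 66.0 and 61.4 with the scrambled guide.

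The fall of GAL1 beside a rise of GAL10 was set against 3 technical or wider explanations. Library scaling moves all genes alike, so it could not by itself set GAL1 and GAL10 apart. Over the deposited, upper-quartile and TMM scalings GAL1 was at −1.81 or lower and GAL10 at 0.78 or higher. These scalings hardly differed, with median log2 folds of all genes of 0.0013, −0.020 and 0.0012, so running them was no further test. A trend with gene length and GC content is argued against for GAL1, which was at −1.86 after that correction (limma adjusted p = 0.0017), while GAL10 kept 0.73 without its call. A fall of the whole regulon as large as that of GAL1 is argued against by a median log2 fold of 0.024 over the 10 other members. Of the pathway genes that glucose represses, GAL7 had a log2 fold of 0.05 (SE 0.156) and GAL2 −0.17 (SE 0.239). GAL2 had too few reads to show a small fall, so a small fall of these genes is not excluded. It also stays open whether part of the GAL1 reads with the scrambled guide came from the noncoding RNA itself, which runs on the strand of GAL1. With the 124.3 normalized reads left in GAL1 this cannot be told apart from a lower GAL1 messenger RNA, because the table gives sums per gene and no read positions. A hypothesis is that inhibition of the noncoding RNA may remove reads from GAL1 and raise GAL10 in these cells. An effect of the bound Cas9 protein itself on either gene cannot be told apart from this, since 1 guide was set against the scrambled one.

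How far the called changes are a library-wide trend with gene length was left open by the length correction, after which 1.96% of the 51 called genes with a length were past the limma threshold. At the p of the last called gene, 8 of the 51 passed with the lower prior degrees of freedom alone (5.66, from 11.5), 28 when the corrected errors came with them, 19 with the corrected folds alone and 8 with the full correction, so the count of lost calls does not measure how much of the changes goes with length. The fold sizes themselves went from a median of 0.314 (median SE 0.060) to 0.236 (median SE 0.050), smaller in 46 and in the same direction in all 51. Against 10000 lists matched on length and expression, the medians of ribosomal protein genes (−0.16, matched middle −0.05) and of ribosome biogenesis genes (−0.06, matched middle 0.034) were at percentile 0. With introns left out of the lengths both stayed at percentile 0, as lower ribosomal protein gene expression beyond gene length and a slower growth programme would need, although the matched middle of the ribosomal protein genes was then −0.12 (95% of matched medians from −0.136 to −0.086). The matched genes were still somewhat longer (474 against 433.5 bp) and lower in expression. With introns counted, the medians of the stress, Gcn4, iron, leucine and copper lists were at 100, 100, 99.97, 99.46 and 0.01, and those of the histone, respiratory, G2/M and mitochondrial ribosomal lists at 11.5, 49.5, 93.3 and 84.1. Matched lists leave out the co-regulation of a list's genes, and reads shared by near-identical members, such as CUP1-1 and CUP1-2 of the copper list. With an estimated correlation the 2 ribosomal lists had camera p-values of 0.178 and 0.175 (adjusted p = 0.686 for both), in a test with few degrees of freedom. A difference in growth state may add to the length trend, which these tests cannot decide. The stress, Gcn4, copper, iron and leucine lists stay without a tested explanation. Without +116 A the medians of the Gcn4, iron and leucine lists were 0.031, 0.021 and 0.051, and without +116 B they were 0.28, 0.14 and 0.15. Whether the length trend or the list changes come from the guide or from these 4 libraries stays open, since the length trend also differed within the groups.

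The lower URA3 with the +116 guide was tested against 3 explanations. A change of the pyrimidine pathway is argued against by a median log2 fold of −0.0064 over its 12 other genes, and a change shared with the other selected marker by LEU2 at −0.058 with an SE of 0.089, although LEU2 ranged from −0.18 to 0.064 with a scrambled library left out. Whether URA3 and LEU2 were carried together is not given in the sources used here. A change in the copies of URA3 alone was therefore not tested and stays open. Whether the single high library, scrambled A, accounts for it stays open, because without it URA3 was at −0.38 with an SE of 0.088 (limma adjusted p = 0.148, between 2.4e-17 and 0.353 over all alternatives).

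The 53 called genes compare with a highest count of 0 in the other splits of the 4 libraries into pairs. Of 3 splits, 1 gave as many, the real one, and 3 splits are too few for a share under 0.05. Each other split put 1 library of each guide in both groups. Any difference between the guides then adds to the spread within the groups and lowers the count, so these splits are no fair baseline.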
